A study of Mus musculus with 2 samples.

How the data were processed

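DNase-seq was done on 2 samples of newborn mouse heart (strain B6NCrl, postnatal day 0), which form 1 group. Per the labels, both libraries were sequenced on a pair of Illumina instrument models, and the series has been superseded by another, which was not used here. Per the text file deposited with each library, peaks and hotspots were called separately for each replicate from that replicate's filtered alignments to mm10. The aligner, the caller, their versions, the filters and the thresholds are not given in the sources used here. How regions were called and filtered can change every count of peaks, since a weak site enters or leaves a list at the caller's threshold.

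The peak lists deposited by the authors give 1 signal value per peak, with no normalization stated. All peaks are 150 bp long, their starts lie on a 20 bp grid, and the value is a whole number that never exceeds 150. From the values it behaves like a number of positions with a read, so it flattens near 150 and is not shown to be scaled for depth. The hotspot lists deposited by the authors give a −log10 of the q-value, from 1.30 to 6 and then exactly 100, which 34.3% of hotspots of replicate 1 and 31.7% of replicate 2 carry. The score column of the deposited hotspot lists is a rounded form of the same value and was not used in tests. Per the deposited files, replicate 1 had 164847 peaks and 152666 hotspots, and replicate 2 had 144867 peaks and 132765 hotspots. Chromosomes 1 to 19, X and Y were analysed, and peaks on the mitochondrial chromosome and on contigs were left out of all comparisons. Read totals are not given in the sources used here, so the depth of each library is unknown and no interval from counts was computed. Precision was limited to the spread between 2 libraries, whose labels name the same donor.

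Coordinates are those of the deposited files and are printed from 1. Chromosome names and lengths of the files were checked against the reference GRCm38.p6, which has the same primary sequence as mm10, and genes and TSSs were taken from GENCODE vM21. The annotation held 55304 genes with a symbol on the analysed chromosomes, 21911 of them protein-coding, and 132629 TSS positions. The symbol Ahsp of the erythroid list was not in this annotation, which left 18 of its 19 genes.

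Peaks of both libraries were compared by overlap of at least 1 bp, against 100 circular shifts of all peaks of a library along their chromosomes. Hotspots were compared by shared base pairs and by the Jaccard index, which is the shared length over the length covered in either library. Each peak was paired with at most 1 peak of the other library for the correlation of values, which is described across peaks with no p. A peak centre within 500 bp of any TSS made a promoter peak, and the remaining peaks were placed in exons, introns or intergenic sequence in that order. Distal peaks have their centre more than 1 kb from every TSS.

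Gene lists for cell types of the heart, cell types foreign to it and programmes of the newborn heart, 31 motifs written as consensus sequences, all main tests and the named genes were fixed before the data were examined. For promoters, the statistic was the share of a list with a promoter peak in both libraries, against 10000 random lists of protein-coding genes of the same decile of CpG observed over expected within 500 bp of the TSS. For distal peaks it was the mean number per gene within 50 kb of the TSS, averaged over both libraries, against 10000 random lists of the same decile of GC content in that window. Both permutation tests were two-sided, with Benjamini-Hochberg adjustment over 26 lists and a threshold of 0.05 for the adjusted p. For motifs, the share of distal peaks with the consensus on either strand was divided by the share in windows of 150 bp centred 1000 bp to either side. This ratio was compared with that of up to 50 versions of the motif with shuffled columns and the same number of CpG, in a one-sided permutation test adjusted over all motifs. Shuffled versions without a match in the flanks of either library have no ratio and were left out.

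Named genes were chosen by a rule with 4 parts. A fixed set of heart and control genes was always named. From each list came the 3 members whose promoter peaks had the highest mean percentile of the value within a library, and in the 3 cardiac lists up to 6 members with no promoter peak in either library. The 5 members of all lists with the most distal peaks were added. From the whole genome came the 10 protein-coding genes with the most distal peaks and the genes nearest the 5 highest peaks and the 5 widest hotspots of both libraries. The text names examples from this set, and some of its members are not reported here. A gene whose TSS lies within 500 bp of a neighbour's is said to share its promoter, and a peak there cannot be assigned to either gene.

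Peak overlap, the gene list tests, the shift of peak values near gene lists and the motif test were tried on simulated data. With 60% of 20000 peaks copied between simulated libraries, 59.9% were recovered net of the overlap after shifting. In 20 simulated rounds over 26 lists, 100% of raised and 65% of lowered lists were called for promoters. Of the other lists, some of which share genes with raised ones, 2.25% were called, which is no clean rate of false calls. For distal peaks these shares were 92.5%, 100% and 2.25%, and for the shift of peak values between libraries near gene lists 97.5%, 100% and 1.75%. Planted changes in distal peaks were larger than the differences from matched genes in the main test below, and genes were simulated independently. These shares need not hold for smaller changes or for genes whose windows share peaks. All 16 motifs planted in simulated peaks of random sequence were called, and none of the others. At least 13 motifs must reach the smallest p that shuffles can give for any to pass. Planting 16 made calls possible, and fewer were not tried, so this recovery does not give the sensitivity in real peaks.

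Alternatives set in advance were a reciprocal overlap of 50%, the stronger 50% of peaks or hotspots, lists of equal length, promoter windows of 200 and 1000 bp, protein-coding TSSs only, gene windows of 100 kb, random lists without matching, flanks 500 bp away, autosomal pairs only and leaving out each replicate. Chosen after seeing the data were random lists matched on CpG and the number of TSSs, counts without peaks in dense runs (at least 15 peaks with starts at most 1 kb apart), counts with peaks under 1 kb apart taken as 1, motifs with repeats masked, and motif ratios with 1 match added to peaks and flanks so that all shuffles count. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and numba 0.67.0, samtools 1.23.1 for the genome index, and matplotlib 3.10.9 for figures.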

Results

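Open chromatin was mapped by DNase-seq in heart tissue of newborn mice of strain B6NCrl (postnatal day 0). In this assay nuclei are digested with DNase I, which cleaves accessible DNA first, and the released ends are sequenced. The series held 1 group of 2 libraries, which the labels number as biological replicates 1 and 2. The labels state no question and name no second tissue, age or treatment. The comparisons made were therefore replicate 1 against replicate 2, and called sites against chance placement, matched random genes or shuffled motifs. Both libraries carry the same donor label, separate biosample labels and no recorded sex, so an SD below measures the spread between these samples, which may be technical. For each library the authors deposited 150 bp peaks and hotspots, which are wider regions of raised cleavage, on genome build mm10. Replicate 1 had 164657 peaks and replicate 2 had 144708 on chromosomes 1 to 19, X and Y. Sequencing depth is unknown, because neither kind of list holds read totals. Each peak carries a value of at most 150 from the authors, with a median of 36 in replicate 1 and 35 in replicate 2. This value served to rank peaks within a library and to describe named sites.

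The highest peaks found in both libraries lay at promoters. The peak at Hjurp, which encodes a histone chaperone of centromeres, lay on chromosome 1 from 88277556 to 88277705 in both libraries and had values of 145 and 148. Peaks next to the transcription start sites (TSSs) of Ensa, Fbxo24, Prr11 and Kctd9 followed, with values from 129 to 137. The widest hotspots shared by both libraries included those at Myc and Jun, which encode growth-related transcription factors. The Myc hotspot spanned 4008 bp in replicate 1 and 5376 bp in replicate 2, and the Jun hotspot 4418 and 3049 bp. Hotspots at Hivep2 and Efna5 were also among the 5 widest, and the remaining hotspot lay 52455 bp from the nearest protein-coding TSS, that of Ppp2r3d on chromosome 9.

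Most peaks of each library were found again in the other. In replicate 1, 70.1% of peaks overlapped a peak of replicate 2 by at least 1 bp, and in replicate 2 the share was 79.8%, a mean of 75.0%. Both shares come from 1 comparison, with 115466 and 115451 overlapping peaks, and differ because the lists differ in length. With lists of equal length they were 73.3% and 73.6%. Shifting the peaks of a library along their chromosomes gave a mean of 1.66% and at most 1.80% over 100 shifts. Promoter peaks were shared more often than distal peaks, which lie over 1 kb from every TSS. In replicate 1, 80.3% of promoter peaks and 67.7% of distal peaks had a partner, and in replicate 2 83.4% and 79.4%. Hotspots covered 44.2 Mb of the genome in replicate 1 and 40.5 Mb in replicate 2, of which 32.4 Mb were common to both. The common length was on average 76.7% of the length covered in a library. As for peaks, the shares of both libraries come from 1 comparison and differ because the covered lengths differ, so no SD is given. The Jaccard index of the hotspots was 0.619, against 0.00852 after shifting. Over the 113417 peaks paired between libraries, the values had a Spearman correlation of 0.919 and a Pearson correlation of 0.928 on the log2 scale, across peaks, which are not independent replicates. In these pairs the median log2 ratio of replicate 2 to replicate 1 was -0.139. The SD of a peak value below includes this offset between libraries. Peaks without a partner were the weaker ones, with a median value of 26 against 44 in replicate 1 and 22 against 40 in replicate 2. Because depth and calling threshold are unknown, the absence of a weak peak from a list does not show a closed site.

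Of all peaks, 20.5% ± 1.35 (SD, n = 2) lay within 500 bp of an annotated TSS, 6.22-fold ± 0.406 more than after shifting, which gave 3.30%. Exons held 5.19% of peaks, introns 42.0% and intergenic sequence 32.3%, the last against 52.2% after shifting. Promoter peaks had higher values, with medians of 54 and 52 in replicates 1 and 2 against 33 and 32 for distal peaks. A promoter peak was present at 65.6% ± 0.610 (SD, n = 2) of the 21911 protein-coding genes, and 13962 genes had a promoter peak in both libraries. This share followed promoter CpG content. It was 3.86% ± 0.420 (SD, n = 2) in the decile of genes with the lowest CpG ratio and 96.3% ± 0.420 in the decile below the highest, and 96.9% of genes of the highest decile had a peak in both libraries. Gene lists were therefore compared with random protein-coding genes of the same CpG decile.

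Genes of the contractile apparatus and of heart metabolism had promoter peaks more often than matched genes. In the sarcomere and Z-disc list, 26 of 28 genes had a promoter peak in both libraries (92.9%), against 45.0% of matched random genes. Random genes matched on the number of TSSs too, an alternative chosen after seeing the data, had 52.6%. Peak values were 105 ± 7.07 at Myh6, the alpha myosin heavy chain, 109 ± 9.19 at Tnnt2, cardiac troponin T, and 112 ± 2.83 at Tnni3, cardiac troponin I (SD, n = 2). The promoter peak of Myh6 (ENSMUSG00000040752.16) lay on chromosome 14 from 54966716 to 54966865 in replicate 1 and from 54966676 to 54966825 in replicate 2, at the 5′ end of the gene, which is on the minus strand. Actc1, cardiac alpha actin, had 106 ± 4.24, and Ttn, the giant spring protein titin, 105 ± 11.3 (SD, n = 2). Neither library had a promoter peak at Myl7, the atrial regulatory light chain. In the list of fetal cardiac genes, 7 of 8 members had a promoter peak in both libraries, against 34.8% of matched genes. Its members Myh7, Tnni1, Myl4 and Myl7 are also in the sarcomere list, so these results are not independent. The fetal cardiac genes Nppa and Nppb, which encode natriuretic peptides, had 58.0 ± 7.07 and 93.0 ± 0 (SD, n = 2). Among genes of fatty acid oxidation and muscle mitochondria, 27 of 28 had a promoter peak in both libraries (96.4%, matched genes 67.6%), with 119 ± 10.6 at the nuclear receptor gene Esrra (SD, n = 2). Acadm, a dehydrogenase of medium-chain fatty acids, had 123 in replicate 1 and 114 in replicate 2, in neighbouring peaks that do not overlap. All 20 glycolysis genes had one, against 80.8% of matched genes, with 118 ± 3.54 at an internal TSS of the hexokinase gene Hk1 (SD, n = 2).

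**Figure D1:**
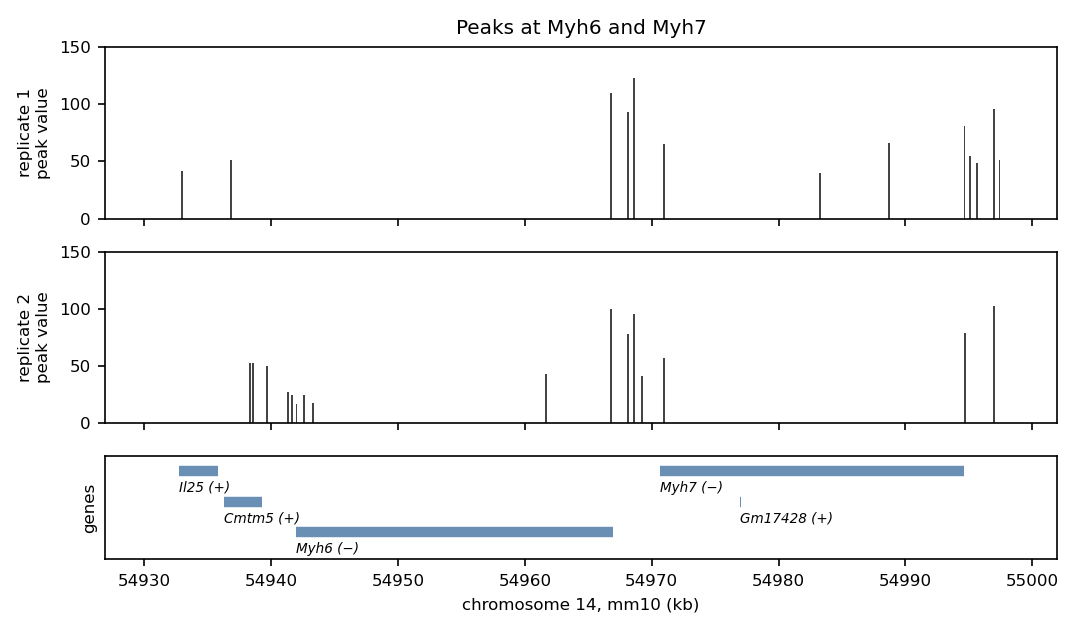
Peaks of replicate 1 (upper panel) and replicate 2 (middle panel) around Myh6 and Myh7 on chromosome 14 of mm10, with position in kb on the x axis, the authors' peak value on the y axis and annotated genes with their strand in the lower panel. Both libraries have a peak at the Myh6 promoter, with values of 110 and 100, and at the Myh7 promoter, with 81 and 79.

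Among ion channel and calcium handling genes, 24 of 27 had a promoter peak in both libraries (88.9%), against 72.2% of matched genes. Values were 109 ± 2.12 at Atp2a2, the calcium pump of the sarcoplasmic reticulum, 98.5 ± 14.8 at its regulator Pln and 75 ± 4.24 at the calcium release channel gene Ryr2 (SD, n = 2). The 3 members without a promoter peak in either library were Hcn2 and Hcn4, which encode pacemaker channels, and Sln, the atrial calcium pump regulator sarcolipin. Cardiac transcription factors had a promoter peak in both libraries at 23 of 25 genes, which did not pass the test because 83.7% of matched genes had one too. Hand2 had 112 ± 12.0, Nkx2-5 101 ± 4.24 and Gata4 100.5 ± 12.0 (SD, n = 2). The highest promoter peaks of Mef2c lay at different TSSs, with 90 in replicate 1 and 84 in replicate 2. The peak that counted for Gata4 lay inside the gene, on chromosome 14 from 63245296 to 63245445, at an annotated alternative TSS. Tbx5 had a promoter peak of value 66 in replicate 1 only, and Irx4, a ventricular transcription factor, had none.

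Genes of the other cell types of the heart wall also had promoter peaks more often than matched genes. The share with a promoter peak in both libraries was 22 of 25 in the endothelial list (88.0%, matched genes 60.4%), 20 of 22 in the fibroblast list (90.9%, matched 53.2%) and 14 of 16 in the smooth muscle and pericyte list (87.5%, matched 61.0%). With the number of TSSs matched too, the matched share for the fibroblast list was 61.0%. Among endothelial genes, values were 62.0 ± 5.66 at the adhesion gene Cdh5, 47.0 ± 5.66 at an internal TSS of Pecam1 and 101 ± 2.12 at an internal TSS of the transcription factor gene Ets1 (SD, n = 2). A fibroblast example was Tcf21 with 49.5 ± 2.12 (SD, n = 2). The highest promoter peaks of Vim, the intermediate filament vimentin, and of the collagen gene Col1a1 did not overlap between libraries and had values of 100 and 48 in replicate 1 and of 98 and 50 in replicate 2. Smooth muscle examples were Acta2, smooth muscle actin, with 76.0 ± 2.83 and Smtn, smoothelin, with 103 ± 8.49 (SD, n = 2). Epicardial genes did not differ from matched genes, with 9 of 15, among them Wt1 with 50 ± 4.24 and Tbx18 with 94.0 ± 9.90 (SD, n = 2).

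Markers of several cell types foreign to the heart had promoter peaks less often than matched genes. Hepatocyte genes had 1 of 24 (4.17%, matched 28.0%), the secreted protein gene Ahsg, and Alb, serum albumin, had none. Lymphoid genes had 2 of 18 (11.1%, matched 39.5%), which were the T cell kinase gene Lck and Foxp3, both at TSSs near another annotated gene. Brain neuron genes had 12 of 26 (46.2%, matched 81.3%), with 113 ± 1.41 at an internal TSS of the kinase gene Camk2a and 72 ± 12.7 at Syn1 (SD, n = 2). The neuronal transcription factor gene Neurod1 had a single low peak of 16, in replicate 2. Male germline genes had 2 of 19 (10.5%, matched 59.0%), namely Dazl and Zpbp, Hox genes 11 of 39 (28.2%, matched 86.9%) and olfactory receptor genes 12 of 1134 (1.06%, matched 10.4%). Not past the test were erythroid genes with 6 of 18 (matched 23.6%), macrophage genes with 2 of 19 (matched 22.0%), Schwann cell and autonomic neuron genes with 5 of 13, skeletal muscle genes with 10 of 29, pancreas and gut genes with 6 of 16 and keratinocyte genes with 5 of 15. No promoter peak was listed in either library at Hbb-bs, an adult beta globin, Gata1, Ptprc, the pan-leukocyte marker, or Myod1, the skeletal muscle regulator. The highest skeletal muscle value was 129 ± 4.95 at Mylpf, whose promoter is shared with Tbc1d10b (SD, n = 2). Of the genes named here and above, Ahsg shares its promoter with Gm30505, Zpbp with Spata48, Neurod1 with Cerkl, Wt1 with Wt1os, Hand2 with Hand2os1, Hk1 with Hk1os, Myl4 with Cdc27 and Myh7 with Gm29015. The peaks given for Nkx2-5, Tbx5, Mef2c, Tnni3, Acta2, Smtn and Lck, and that of Col1a1 in replicate 2, also lay inside the gene, more than 1 kb from its 5′ end, at other annotated TSSs. All 21 cell cycle, all 24 ribosomal protein and all 19 immediate-early genes had a promoter peak in both libraries, as did 11 of 13 imprinted genes, but matched genes of these lists had one at 83.7% to 94.7% and none of these lists passed.

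Each list was tested against 10000 random lists of matched genes (permutation test, two-sided) with Benjamini-Hochberg adjustment over 26 lists, and 8 lists were higher and 6 lower. Some lists share genes, so their calls are not independent. The adjusted p was 0.000433 for the sarcomere, fatty acid oxidation, brain neuron, male germline, Hox and olfactory lists, whose unadjusted permutation p of 0.0001 is the smallest these lists can give. It was 0.000743 for fibroblast, 0.00130 for endothelial, 0.00491 for fetal cardiac, 0.00520 for lymphoid, 0.00780 for hepatocyte, 0.0145 for ion channel, 0.0346 for smooth muscle and 0.0429 for glycolysis genes. For cardiac transcription factors it was 0.345. Random lists treat genes as independent, so p is too small for lists whose genes lie in clusters, such as Hox and olfactory receptor genes. In the same permutation test, calls were lost with a 1000 bp window for glycolysis (adjusted p = 0.0916), smooth muscle (0.0874), lymphoid (0.252) and hepatocyte genes (0.162), with unmatched lists for fetal cardiac (0.290), smooth muscle (0.0821) and brain neuron genes (0.0831), with the stronger 50% of peaks for smooth muscle (0.205), without replicate 1 for smooth muscle (0.0660) and lymphoid genes (0.143), without replicate 2 for ion channel (0.0516) and glycolysis genes (0.0643), and for glycolysis genes with the number of TSSs matched too (0.0889), which was chosen after seeing the data.

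**Figure D2:**
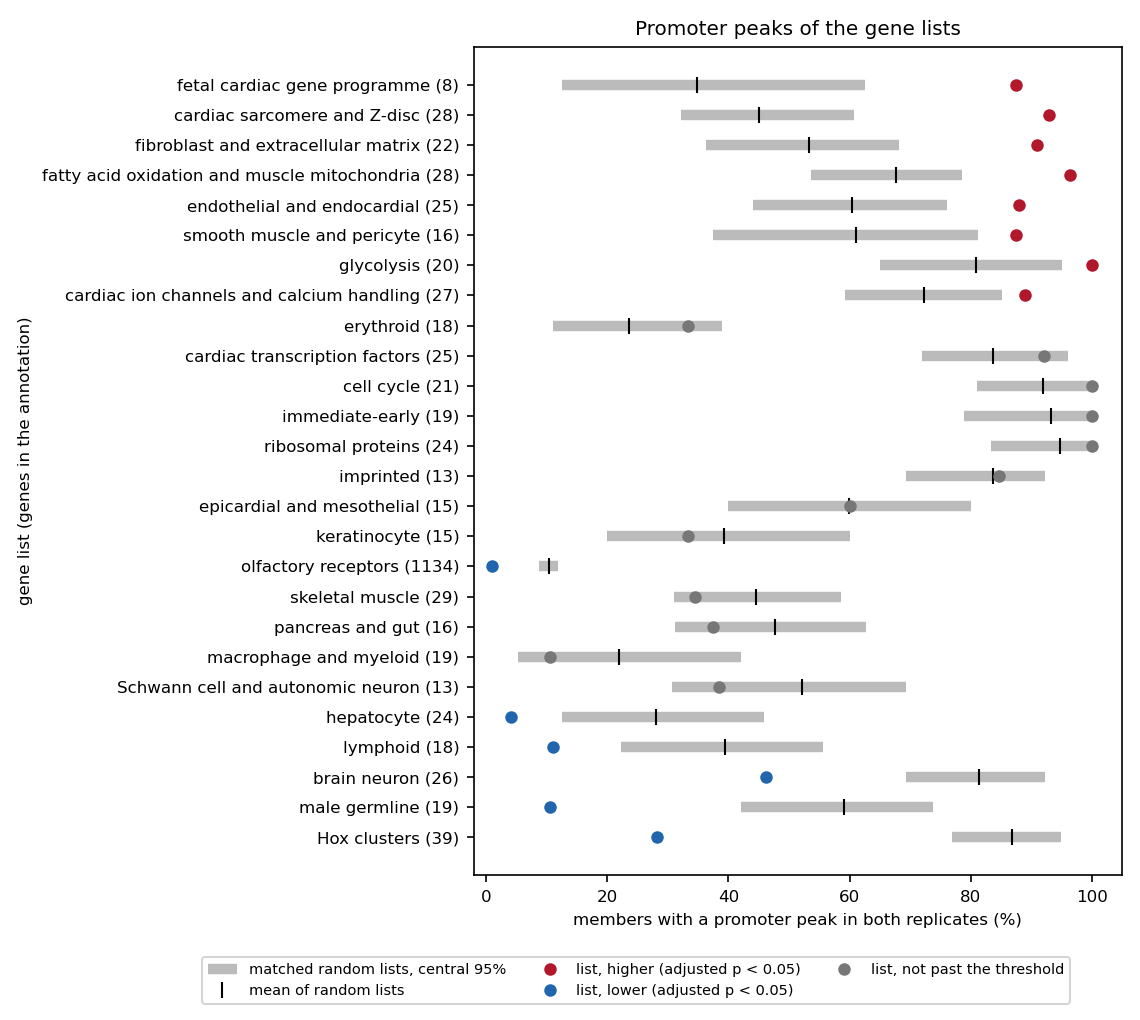
Share of each gene list with a promoter peak in both libraries, in % on the x axis, with the list and its number of genes on the y axis. Points are the lists, red where higher and blue where lower after adjustment, and grey bars with a tick give the central 95% and mean of matched random lists, so the 28 sarcomere genes stand at 92.9% against 45.0% and the 39 Hox genes at 28.2% against 86.9%.

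Distal peaks were denser around genes of heart muscle and of the other heart cell types. Within 50 kb of their TSSs, sarcomere genes had 11.5 ± 2.27 distal peaks per gene (SD, n = 2), against 6.90 for random genes matched on GC content, a 1.67-fold excess. Fibroblast genes had 9.41 ± 0.450 against 5.66, ion channel genes 8.76 ± 1.34 against 5.52, endothelial genes 9.36 ± 0.905 against 6.68 and smooth muscle genes 9.75 ± 0.972 against 6.83 (SD, n = 2). Cardiac transcription factors, which did not stand out at promoters, had 8.50 ± 0.933 against 6.15, and fatty acid oxidation genes 8.77 ± 0.934 against 6.70 (SD, n = 2). Immediate-early genes, which respond to stimulation within minutes, had 11.4 ± 0.0372 against 7.74 (SD, n = 2). Hox genes were lower, with 4.42 ± 0.816 against 8.11, as were olfactory receptor genes, with 1.04 ± 0.102 against 1.99 (SD, n = 2). The windows of clustered genes overlap and count the same peaks. Counts were not corrected for how much of a window lies over 1 kb from every TSS, and matching on GC does not adjust for that. None of the lists of blood, skeletal muscle, neuron, liver, gut, germline or skin genes passed, and hepatocyte genes had 5.63 ± 0.177 against 5.56 (SD, n = 2). Fetal cardiac genes (9.38 ± 1.77 against 7.53), epicardial genes (6.13 ± 0.660 against 5.66), glycolysis genes (7.30 ± 1.06 against 7.54) and cell cycle genes (8.12 ± 0.707 against 7.06) did not pass either, nor did ribosomal protein and imprinted genes (SD, n = 2).

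Cardiac genes were among the single genes with many distal peaks. Gata4 had 23 distal peaks in replicate 1 and 38 in replicate 2. Replicate 2 had a run of 17 peaks inside Gata4, where replicate 1 had 2. Myl2, the ventricular light chain, had 17 in both, Atp2a2 had 14.5 ± 0.707 and Ryr2 12.5 ± 0.707 (SD, n = 2). Tnnt2 and the adjacent gene Lad1 had the most of all protein-coding genes in replicate 1, with 64 and 66, but only 15 and 16 in replicate 2. Replicate 1 had a run of 38 peaks on chromosome 1 from 135833936 to 135852645, over the whole Tnnt2 gene, where replicate 2 had 3, and beside it a run of 27 peaks from 135854716 to 135864145, where replicate 2 had 5. High numbers found in both libraries were those of Tmem107 (36 and 37), Vamp2 (35 and 36) and Per1, a clock gene (28 and 29), which are neighbours on chromosome 11 and share much of 1 window. Clic4 had 29 and 31, Irf2bp2 26 and 34 and Adamtsl4 31 and 25.

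**Figure D3:**
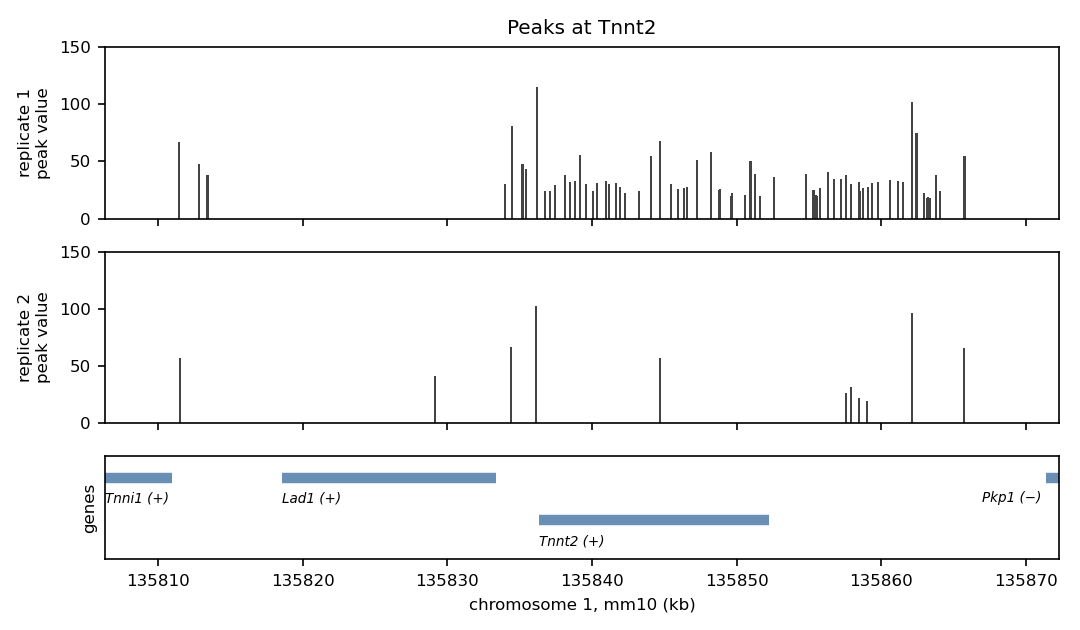
Peaks of replicate 1 (upper panel) and replicate 2 (middle panel) around Tnnt2 on chromosome 1 of mm10, with position in kb on the x axis, the authors' peak value on the y axis and annotated genes with their strand in the lower panel. The promoter peak of Tnnt2 stands at 115 and 102, and the run of 38 peaks over the gene in replicate 1 faces 3 peaks in replicate 2.

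In the permutation test against 10000 matched lists, 8 of 26 lists were higher and 2 lower. The adjusted permutation p was 0.000433 for the sarcomere, ion channel, fibroblast, immediate-early, Hox and olfactory lists, and 0.00371 for endothelial, 0.00780 for cardiac transcription factor, 0.0116 for smooth muscle and 0.0169 for fatty acid oxidation genes. As for promoters, random lists treat genes as independent, so p is too small for the clustered Hox and olfactory receptor genes. In the same permutation test, the call was lost for fatty acid oxidation genes with a 100 kb window (adjusted p = 0.0771) and for Hox genes with unmatched lists (0.148). Without peaks in dense runs, an alternative chosen after seeing the data, sarcomere genes had 10.4 distal peaks per gene against 6.87.

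**Figure D4:**
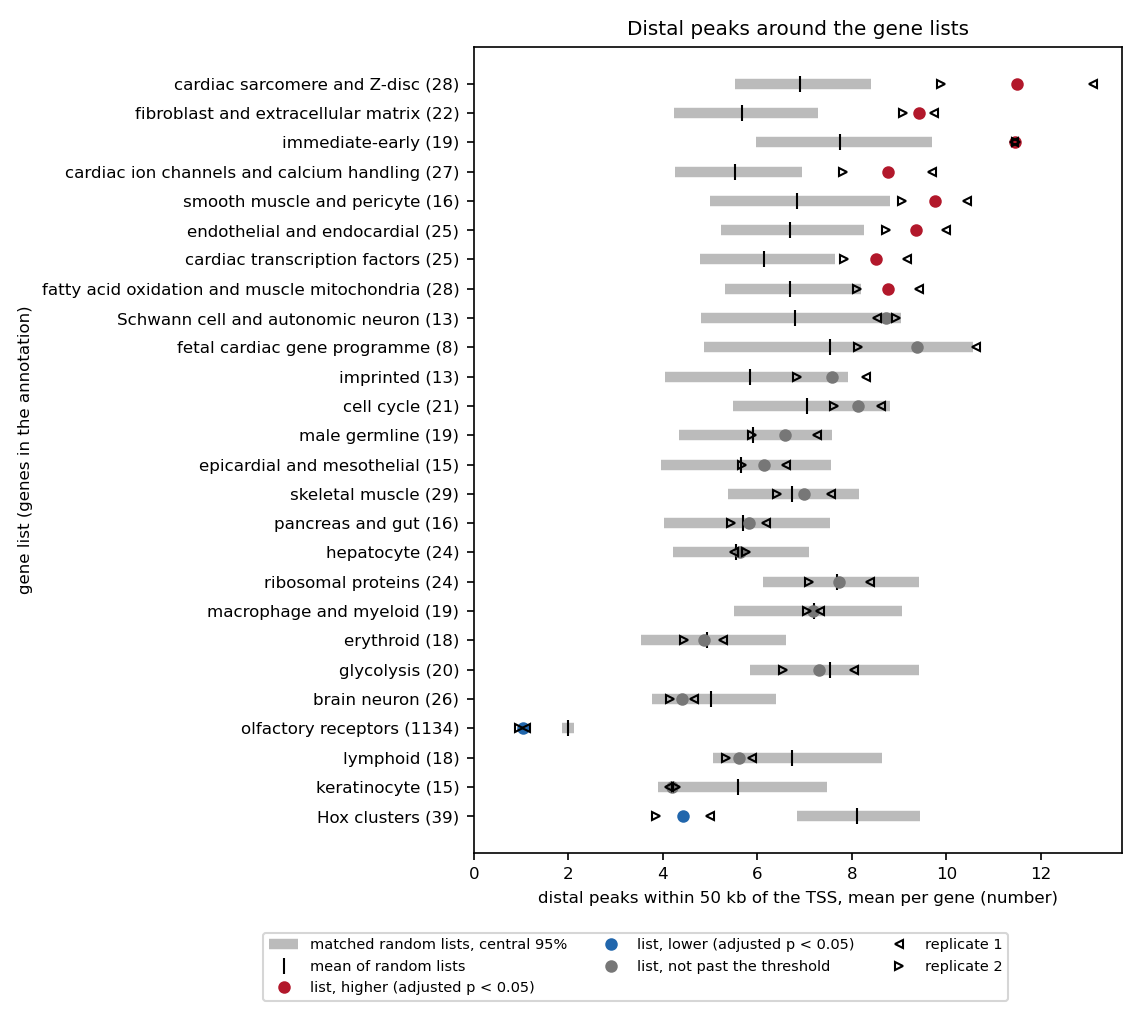
Mean number of distal peaks within 50 kb of the TSS per gene (x axis) for each gene list, named with its number of genes on the y axis. Points are means of both libraries, red where higher and blue where lower after adjustment, triangles are the libraries, and grey bars with a tick give the central 95% and mean of matched random lists, so sarcomere genes lie at 13.1 in replicate 1 and 9.89 in replicate 2 against 6.90.

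Several consensus motifs, among them those of MEF2, GATA, ERG, AP-1 and CTCF, were more frequent in distal peaks than in sequence 1000 bp to either side. Those of NKX2-5, HAND and T-box factors did not pass, and a match does not show which factor binds. The motif of MEF2, a muscle regulator, was present in 4.98% ± 0.170 of distal peaks, 1.80-fold ± 0.0528 its share in flanks, and that of GATA factors in 8.75% ± 0.232, 1.42-fold ± 0.0283 (SD, n = 2). TEAD (1.81-fold ± 0.0680), MEIS (1.70-fold ± 0.0182) and the SRF CArG box of contractile genes (2.49-fold ± 0.308) were also higher (SD, n = 2). Of motifs used in vessels, blood and other tissues, ERG reached 2.17-fold ± 0.025, ETS 2.58-fold ± 0.141 and the combined GATA-TAL motif 1.56-fold ± 0.0613 (SD, n = 2). The last contains GATAA, the core of the GATA motif, which shuffling its columns breaks up. GATA sites alone could therefore exceed the shuffles, so this pass does not show a combined site. PU.1 (2.02-fold ± 0.115), KLF1 (1.37-fold ± 0.0519), RUNX (0.994-fold ± 0.04999), SOX (1.22-fold ± 0.0191) and FOX (1.01-fold ± 0.0191) did not pass (SD, n = 2). AP-1, the motif of Fos and Jun dimers, was in 6.42% ± 0.00222 of distal peaks, 2.46-fold ± 0.0138, and CREB stood at 3.94-fold ± 0.00866 (SD, n = 2). Ratios were highest for the long motifs of REST, 49.0-fold ± 8.80, of the architectural factor CTCF, 38.4-fold ± 7.82, and of NFI, 12.9-fold ± 2.97 (SD, n = 2). The REST motif was in only 0.00398% of flanks, and with flanks 500 bp away REST stood at 146-fold ± 106 and NFI at 7.58-fold ± 1.17 (SD, n = 2). The MYOD E-box, which several factor families can bind, was 2.44-fold ± 0.0975 higher (SD, n = 2). The motifs of NKX2-5 (4.56% ± 0.0631 of peaks, flanks 3.52%), HAND (1.11-fold ± 0.0199) and T-box factors (0.736-fold ± 0.0431) did not pass, nor did those of the liver factors HNF4 (1.10-fold ± 0.0426) and HNF1 (0.149-fold ± 0.0156) (SD, n = 2).

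Of 31 motifs, 14 passed the permutation test against shuffled versions with the same number of CpG (one-sided, Benjamini-Hochberg), with an adjusted p of 0.0468 for 13 of them and 0.0471 for REST. With 50 shuffles the smallest unadjusted permutation p is 0.0196, so at least 13 motifs had to exceed every shuffle for any to pass. In all, 15 motifs exceeded every shuffle, and of these the SP motif did not pass. It allows only few distinct shuffles with the same number of CpG, so its p could not reach the threshold. With flanks 500 bp away or with the stronger 50% of peaks none passed, where the smallest adjusted permutation p was 0.0507, although the motifs called above exceeded every shuffle there too, except SRF with flanks 500 bp away (2.21-fold, highest shuffle 2.44) and ETS with the stronger 50% of peaks (2.64-fold, highest shuffle 2.81). Shuffles without a match in flanks have no ratio and were left out, so REST kept 46 of its 50. With 1 match added to peaks and flanks, an alternative chosen after seeing the data, all 50 counted, REST stood at 40.1-fold and its adjusted permutation p was 0.0405. Distal peaks were richer in GC than flanks, with 49.9% against 44.8% in replicate 1.

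**Figure D5:**
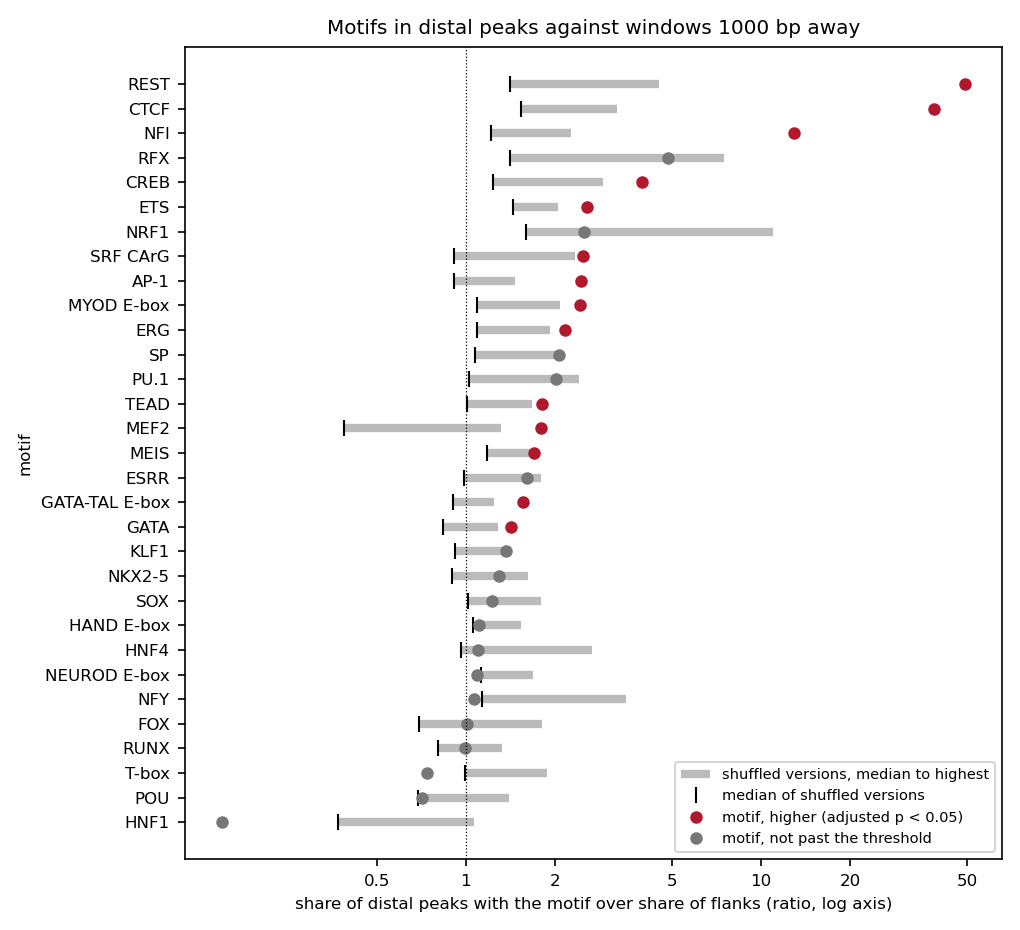
Ratio of the share of distal peaks with a motif to the share of windows 1000 bp away (x axis, log scale), mean of both libraries, for each of 31 motifs on the y axis. Points are motifs, red where past the adjusted threshold, and grey bars run from the median, marked by a tick, to the highest of the shuffled versions, so MEF2 lies at 1.80 against a highest shuffle of 1.32 and CTCF at 38.4 against 3.25.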

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

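The test of extra reads in dense runs of peaks, the test of depth for chromosome Y and the counts without peaks in dense runs were chosen after the result was seen. Peaks outside the analysed chromosomes appear in both lists. The mitochondrial chromosome carried 17 peaks in replicate 1 and 17 in replicate 2, all with the same start and value, 9 of them at 150, the highest value in either library. On unplaced or unlocalized contigs there were 173 peaks in replicate 1 and 142 in replicate 2.

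In a few places a library had a long run of closely spaced peaks that the other library lacked. Of 11 runs in replicate 1, 8 had under 50% as many peaks in replicate 2, among them those over Tnnt2 (38 against 3), Mid1 (40 against 5) and the Ugt1a genes (22 against 4), and of 12 runs in replicate 2, 6 did, among them one inside Gata4 (17 against 2). More reads over the whole region, from extra DNA copies or foreign DNA, would raise shared peaks there, but the 47 pairs inside the runs were shifted by 0.039 on the log2 scale (SE 0.034) towards the library with the run, below the bound of 0.3. Only peaks called in both libraries entered, in runs chosen for missing peaks, which can make the shift smaller, and high values flatten. The mean also pools runs at different places, so it does not exclude extra reads at a single run such as that over Tnnt2. Splitting of a region that both libraries call accessible stays open, as the hotspots of the other library covered 17.1% of the 292 run peaks, but the bound of 50% set on that share was wrong, because 0 hotspots lack a peak and the runs were chosen for missing peaks. What makes these runs stays open, and no biological explanation was tested because the series has 1 group.

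Replicate 2 had fewer distal peaks (103652 against 121677), and its number over that of replicate 1 differed between gene lists, from a ratio of 0.755 near sarcomere genes, where dense runs widened the gap (13.1 and 9.89 distal peaks per gene in replicates 1 and 2, but 11.25 and 9.64 without peaks in dense runs), to 1.05 near hepatocyte genes. A different share of cardiomyocytes could shift peak values near sarcomere genes, where the mean over paired peaks, net of value, was -0.0039 on the log2 scale (SE 0.023) in replicate 2 against replicate 1. That test set its bound on passing a threshold, which was the wrong bound, since a missed threshold does not exclude a small shift, so this explanation stays open. A difference in depth or saturation alone needs no list to shift once peaks are matched on value, and 0 of 26 lists did (smallest adjusted permutation p = 0.712). In simulated data this test recovered 100% of lowered lists, for the size of shift planted there. It used only peaks paired between libraries, so peaks missing from a library, which make the difference in number, did not enter. Whether depth alone explains the numbers therefore stays open too. No biological explanation was tested, as the series has 1 group.

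Chromosome Y peaks had lower values in replicate 2. At the promoters of Kdm5d, Uty, Eif2s3y and Ddx3y the values were 52, 80, 56 and 73 in replicate 1 and 26, 55, 40 and 57 in replicate 2. Lower depth at weak peaks is argued against, since the 37 paired Y peaks fell by 0.28 on the log2 scale (SE 0.083) relative to autosomal pairs of the same replicate 1 value, below the 2.5th percentile of -0.14 in random sets. A lower share of male tissue would lower Y values and could raise X values, but the 2521 X pairs were shifted by -0.011 on the log2 scale (SE 0.0078). The bound set on X was wrong, because the inactive X of female cells is mostly closed and need not raise X peaks, so a different mix of sexes stays open, the sex not being recorded, and no other biological explanation was tested.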

How the results depend on the processing

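The alternatives with TSS number matched, without dense runs, with close peaks counted once, with repeats masked and with 1 match added were chosen after the results were seen. The stronger 50% of peaks raised the mean overlap between replicates from 75.0% to 82.4% and the promoter share from 20.5% to 29.5%. Mean overlap was lower, 69.9%, with a reciprocal overlap of 50%, and 73.4% with lists of equal length. The promoter share also followed the window, with 27.2% at 1000 bp and 13.7% at 200 bp, was 18.0% with protein-coding TSSs only, and ranged from 19.6% to 21.5% without each replicate in turn. The mean share of hotspot length common to both libraries was 76.7%. It was 77.2% with the stronger 50% of hotspots and 77.0% with lists of equal length. The Spearman correlation of values lay between 0.918 and 0.920 under every alternative tried. Like peak overlap, hotspot overlap and this correlation cannot be computed with a replicate left out. At promoters, 4 of the 8 higher lists and 3 of the 6 lower lists kept their call in all 6 alternatives. Without matching on CpG, 10 promoter lists were lower instead of 6, and erythroid genes turned from 9.76 percentage points above to -30.6 below the random mean (adjusted permutation p = 0.0148), because unmatched random genes have more CpG-rich promoters. Higher promoter lists numbered from 6 to 10 over the alternatives. For distal peaks, 7 of 8 higher lists and 1 of 2 lower lists kept their call in all 7 alternatives, and 1 list was lower without matching on GC. Distal calls were gained by Schwann cell genes without replicate 1 (adjusted permutation p = 0.0378), by fetal cardiac genes with a 100 kb window (0.0172), by 3 lists with the stronger 50% of peaks (0.0119 for fetal cardiac and imprinted genes, 0.0430 for keratinocyte genes, which were lower) and by 4 lists without matching (0.0221 to 0.0382), and promoter calls by Schwann cell genes with the stronger 50% (lower, 0.0173) and by 8 lists besides erythroid genes without matching. The number of motifs called fell from 14 to 0 with flanks at 500 bp and to 0 with the stronger 50% of peaks, where the same motifs still exceeded every shuffle except SRF in the former and ETS in the latter, 13 were called without replicate 1 and 13 without replicate 2, where REST had adjusted permutation p of 0.0540 and 0.0515, 16 with repeats masked and 15 with 1 match added. No paired analysis was possible because the series has 1 group. Depth is unknown and limits which weak peaks are listed. For the other values that moved, the cause was not tested.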

Other observations

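The masking of repeats was chosen after the result was seen. Distal peaks near cardiac genes were richer in GATA motifs than those near other genes. Within 50 kb of the 80 genes of the 3 cardiac lists (transcription factors, sarcomere, ion channels), 12.1% ± 0.195 of distal peaks (SD, n = 2) had a GATA motif, against 7.47% near matched random genes, a 1.62-fold excess (adjusted permutation p = 0.0434 over 217 tests, higher in 2 of 2 libraries). This was the only one of the 217 tests to pass. ERG motifs were at 2.77% ± 1.03 near the same genes (SD, n = 2), against 6.12%, which did not pass (adjusted permutation p = 0.0825). Near the 25 endothelial genes, SOX motifs were in 3.83% ± 0.234 of distal peaks (SD, n = 2) against 1.11%, which did not pass either (adjusted permutation p = 0.0825). All 217 tests pooled peaks over genes, so genes with many distal peaks, such as Tnnt2 with 64 in replicate 1, weigh more. Peaks in overlapping windows were counted more than once, and peaks in dense runs were not left out.

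The hypothesis that MEF2 sites concentrate near cardiac muscle genes was tested by the same share. It was 6.06% in replicate 1 and 7.89% in replicate 2, a mean of 6.98% against 3.77%, 1.82-fold, with an adjusted permutation p of 0.0506, just short of the threshold, so the hypothesis stays open. ERG sites may concentrate near endothelial genes, where the share was 12.8% ± 1.18 (SD, n = 2) against 6.09%, 2.11-fold, with the same adjusted permutation p of 0.0506. AP-1 sites near immediate-early genes were 1.45-fold the random share, with an adjusted permutation p of 0.877, which neither shows nor excludes a concentration.

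With repeats masked in peaks and flanks, the ESRR motif (2.45-fold) and the RFX motif (16.5-fold) were called as well. Repeats made up 13.2% of distal peak sequence in replicate 1 and 12.1% in replicate 2, against 24.9% or more of flanks.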
